A study of Mus musculus with 24 samples.

How the data were processed

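RNA was measured in liver and kidney of mice that lacked Nudt12 and in wild-type mice, and in livers of both genotypes collected around the day. Total RNA (500 ng) was depleted of ribosomal RNA and made into stranded libraries, which were sequenced as single reads of 100 bases. GEO lists 24 samples in 6 groups, and 23 libraries were analysed here. The libraries came from 3 wild-type and 3 knockout livers, 2 wild-type and 3 knockout kidneys, and 6 wild-type and 6 knockout livers of the time course; wild-type kidney replicate 3 was not analysed here.

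The authors deposited estimated counts per gene that had already been normalized, as values that are never negative (a normalized signal), in 3 tables of 50765 genes each, per the file headers. Salmon 0.12.0, R 3.6.0, DESeq, DESeq2 1.24.0 and the mouse build GRCm38 are listed in the submitters' processing notes, with no role for any of them. Within a table the library values divided by a common step per library came out whole for only 6.32 to 14.16% of low values (to within the rounding of the files), so the reads could not be recovered and tests on counts were not run. Each table was normalized separately, so levels in different tables are not on one scale. Tests of genes and lists were made within a table or on differences of within-table effects. The internal time below is the exception, since it sets levels of the liver cohort against mean levels of the time course. The tables also hold the authors' log2 fold change and adjusted p-value for knockout over wild type, per the file headers; how these 2 columns were computed is not given in the sources used here. The sums of the normalized counts ran from 16.9 to 27.8 M (mega, 1e+06) per library. Divided by the commonest step among low values, this gives about 12.5 to 28.6 M estimated reads, an approximate depth that limits what can be said of genes with values of a few counts.

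Coordinates were taken from GENCODE vM21 on GRCm38. Of the 50765 gene identifiers, 49630 matched with their version and 862 more without it, and 50455 of the genes lay on the same chromosome in the tables and in that annotation.

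Groups came from the labels. Each comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a trend in the prior variance, over genes with a mean of at least 1, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. All adjusted p-values are from limma unless another source is named. The fit for counts that had been foreseen was not possible in this unit, and limma was the fallback fixed with it. The time course model had genotype and time as a factor of 6 levels, because the replicate numbers of the time course mark shared times of collection. The numbers of the liver and kidney libraries were given in order of accession, name samples only and pair nothing. Rhythms were tested in the time course with a cosine and a sine of 24 h plus genotype, and differential rhythm by the interaction of these terms with genotype. The difference of the knockout effects between liver and kidney, and between the liver cohort and the time course, was tested as an interaction in a joint limma fit.

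Lists of genes (54, among them a core clock list of 23 genes) were fixed before the data were examined, as were the tests, the named genes and most of the alternatives below. Lists with at least 3 tested members were tested with camera, with a preset correlation of 0.01 between genes, and again with the correlation estimated from the data and with fry, which asks whether the members move one way on balance without reference to other genes. The text names Nudt12, the genes past the threshold (up to 10 in each direction), the 5 genes with the smallest p where fewer than 5 passed, the core clock list, up to 4 members of each other list by p, and the 10 rhythmic genes with the smallest p; a few genes under this rule are not reported here. Genes named outside that rule were chosen after their values were seen: 6 genes of the authors' deposited table, genes given library by library beside a list, and those of the closing part.

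The internal time of the livers without a time label was read on a grid of 0.1 h. It was the time at which the fitted curves of the rhythmic clock genes correlated best with the values of a library. From each value the mean level of that gene in the time course was subtracted first. The error of the internal time came from the time course with each time point left out in turn. It does not cover differences between the separately normalized liver cohort and time course. Genes within 20 Mb of Nudt12 were compared with all others by Fisher's exact test.

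Scripts for the fits were tested on simulated data in which 200 genes changed by known amounts, drawn on the real genes. At a 4-fold change limma called 61.3% of the changed genes in the kidney design (21323 genes), 63.6% in the liver design (18484 genes) and 75.4% in the time course design (18396 genes). At a 2-fold change it called 28.1, 10.6 and 52.3%. Where far fewer genes pass, as in the genotype comparisons below, the adjustment is stricter. These shares may therefore overstate what limma could find there. The rhythm test (18702 genes) called 58% of genes with a log2 amplitude of 1 and 87.5% at an amplitude of 2.

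Alternatives were quantile normalization, no filter on low values, pseudocounts of 0.1 and 5, both tissues in 1 fit, no term for time, cosine terms in place of the time factor, other windows, other reference genes, and each library or time point left out. A filter at a mean of at least 10, robust variance priors, and time course fits without the times at which pancreatic transcripts were measured were added after seeing the data, as was the extension of some other alternatives to further results. Tests that need counts (edgeR, DESeq2, limma-voom and other size factors) and a single fit of knockout effects in both liver cohorts together, which was foreseen for counts only, were not run. Labels do not say whether the liver and kidney libraries came from the same mice. P-values of limma for single genes measure the spread between these samples. With both tissues in 1 fit they rest on a spread pooled over liver and kidney, not on that of livers or kidneys alone. Those of camera with the preset correlation set the members of a list against other genes, and Fisher's exact test counts genes. Both therefore say little of the spread between mice. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and data.table (1.17.8) and jsonlite (2.0.0) in R, were used for tables and figures.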

Results

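Nudt12 encodes a nudix hydrolase of peroxisomes and cytoplasm that acts on NAD and NADH and removes NAD caps from RNA. Mice homozygous for a 58 bp deletion in exon 6 of Nudt12 were compared with wild-type mice. Liver and kidney were taken at 3 to 4 months of age. A separate set of livers was taken at 4 to 6 months, after 10 days of acclimation to 12 h of light and 12 h of dark, every 4 h at zeitgeber times (ZT, hours after lights on) 0, 4, 8, 12, 16 and 20, with 1 library per genotype and time. Normalized estimated counts summed to 25.1 to 27.8 M (mega, 1e+06) in the kidney libraries, 24.1 to 27.5 M in the liver libraries and 16.9 to 19.9 M in the time course. Values above 0 were listed for 22668 to 23423 genes in kidney, 19517 to 20437 in liver and 18293 to 20038 in the time course. The 7SL RNA gene Rn7s1 took 5.65 to 15.15% of each library. Mitochondrially encoded genes took 16.06% of the library of wild-type kidney 1 and 7.4 to 9.54% of the other 4 kidney libraries, 7.39% of that of wild-type liver 1 and 2.27 to 4.54% of the other 5 livers of the cohort, and 6.72 to 15.5% of the time course libraries. Depth was lowest in the wild-type library of ZT8, at about 12.5 M estimated reads.

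Nudt12 (ENSMUSG00000024228.12) lies on chromosome 17 from 58999618 to 59013372 on the minus strand of GRCm38, and exon 6 of the 7 exons of its coding transcript spans 59003329 to 59003528 (200 bp). Its transcript fell in each comparison. In liver it was 1158 ± 160 in the wild type and 226.0 ± 12.9 in the knockout (normalized counts, mean ± SD, n = 3 and 3). In kidney the values were 1548 ± 49.7 and 306.7 ± 43.9 (n = 2 and 3), and in the time course 957 ± 212 and 209.0 ± 36.0 (n = 6 and 6). The knockout level was 19.5% of the wild type in liver, 19.8% in kidney and 21.8% in the time course. The log2 fold changes were -2.34 in liver (SE 0.17, adjusted p = 0.00944), -2.34 in kidney (SE 0.16, adjusted p = 0.0404) and -2.17 in the time course (SE 0.19, adjusted p = 0.0211), and every knockout library lay below every wild-type library of its set. The authors' deposited table gives -2.32, -2.31 and -2.17 for the same contrasts. The adjusted p rose above the threshold in liver without knockout 2 (0.072). It also did so in kidney without any 1 library (0.241 and 0.289 without wild type 1 or 2, and 0.0953, 0.457 and 0.0811 without knockout 1, 2 or 3), and in the time course without ZT0 (0.196), ZT4 (0.121), ZT12 (0.108), ZT16 (0.19) or ZT20 (0.0554).

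**Figure D1:**
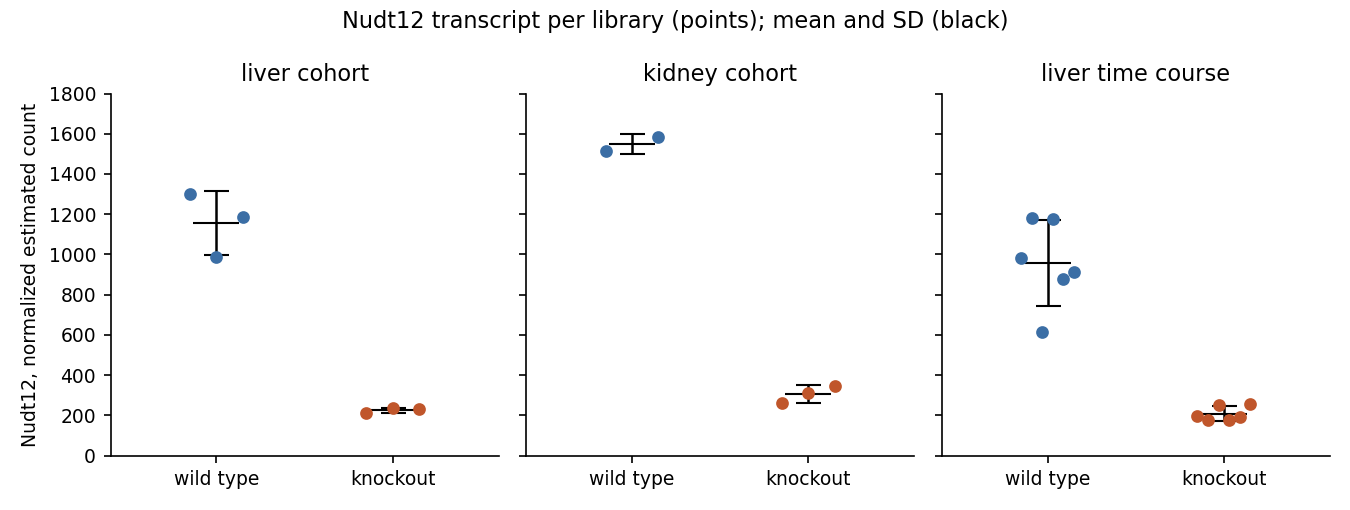
Nudt12 transcript in each library (points, normalized estimated counts, vertical axis from 0) for wild type and knockout in the liver cohort, kidney and liver time course, with mean and SD in black. The knockout means are 226.0 in liver, 306.7 in kidney and 209.0 in the time course, against wild-type means of 1158, 1548 and 957.

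In the liver cohort, which asks what changes in liver without Nudt12, 3 of 19088 genes passed the threshold: Nudt12, Eci3 and Gm30948. Eci3, which encodes a peroxisomal enoyl-CoA isomerase, rose from 1.37 ± 1.52 to 131 ± 54.3 (log2 fold change 5.95, SE 0.59, adjusted p = 0.047, higher in 3 of 3 knockouts than in any wild type). With wild types this close to 0 its fold change depends on the pseudocount, at 7.44 with 0.1 (adjusted p = 0.147) and 4.38 with 5 (adjusted p = 0.0231), and over its 13 alternatives the adjusted p ran from 0.00035 to 0.147. In the time course Eci3 varied between libraries of the same genotype, with wild types at 45.8, 73.1 and 63.3 at ZT0, ZT12 and ZT16 but listed at 0 at ZT4 and ZT8, and knockouts from 1.07 at ZT0 to 116 at ZT16. Gm30948, a predicted gene, rose from 10.4 ± 0.51 to 585 ± 519 (5.33, SE 0.54, adjusted p = 0.047), with knockout values of 255, 317 and 1183. Next by p, and not past the threshold, came Upp2 (uridine phosphorylase) at 3233 ± 854 and 13598 ± 1967 (2.10, adjusted p = 0.0589), Ciart (adjusted p = 0.0768), Arntl and Saa2 (adjusted p = 0.0857 each). At an unadjusted p under 0.05 there were 1526 genes, where 954 would be expected by chance. The groups did not overlap for 2659 genes (13.9%, where chance gives 10%). The authors' deposited table lists 211 genes below an adjusted p of 0.05 in liver (93 higher, 118 lower), and all 211 had the same sign here. The count of 3 genes became 55 with both tissues in 1 fit, 38 without wild-type liver 1, 7 without wild type 2, 14 without knockout 1, 0 without knockout 2 and 5 without knockout 3. Eci3 lost its call without wild type 3 (adjusted p = 0.12) or knockout 1 (0.0556), 2 (0.111) or 3 (0.132), and Gm30948 lost it without wild type 2 (0.156), wild type 3 (0.122) or knockout 2 (0.0856). Gm30948 also lost it with a pseudocount of 0.1 or 5 and with a mean of at least 10 required, and was called in 7 of its 13 alternatives.

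The core clock genes, whose feedback loops form the daily oscillator of cells, were with the acute-phase genes the lists with the most changed members in liver. Adjusted over the list alone, 14 of the 23 members passed (11 higher and 3 lower in the knockout), while 0 passed over all genes tested with limma. With both tissues in 1 fit, which pools the spread of liver and kidney, 5 of them were among the 55 liver genes that passed over all genes. These were Usp2 (adjusted p = 0.0145), Ciart (0.0156), Arntl (0.0158), Tef (0.0183) and Per3 (0.0379). Arntl, Ciart and Usp2 also passed without wild type 1, and Arntl and Ciart with no filter on low values. Among the repressors and outputs driven through E-boxes, Ciart rose from 11.2 ± 3.97 to 268 ± 142 (log2 fold change 4.36, SE 0.50, n = 3 and 3), Dbp from 157 ± 211 to 1394 ± 170 (4.12, SE 0.83), Per2 from 87.1 ± 59.9 to 527 ± 155 (2.95, SE 0.68) and Tef from 1013 ± 532 to 4784 ± 1090 (2.34, SE 0.35). Per3, Usp2, Bhlhe41, Nr1d2, Per1, Cry2 and Csnk1d also rose. Arntl, the gene for the activator BMAL1, fell from 401 ± 144 to 37.0 ± 17.2 (-3.43, SE 0.41), Nfil3 fell from 592 ± 270 to 179 ± 56.3 (-1.68, SE 0.35) and Clock from 1760 ± 173 to 912 ± 268 (-0.99, SE 0.24). The members that did not pass included Npas2 (-1.77), Hlf, Nr1d1 (0.58), Cry1 (-0.57) and Rora. The count stayed between 12 and 16 with any 1 library left out. Camera called the core clock list (adjusted p = 6.88e-06; adjusted p = 0.409 with an estimated correlation), the list of E-box driven repressors and PAR-bZIP factors (12 of 12 members higher, median 2.48, adjusted p = 1.05e-16; 0.302 with an estimated correlation) and, downward, the list of the Bmal1 arm (5 of 6 lower, median -1.33, adjusted p = 0.000537; 0.302 with an estimated correlation).

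**Figure D2:**
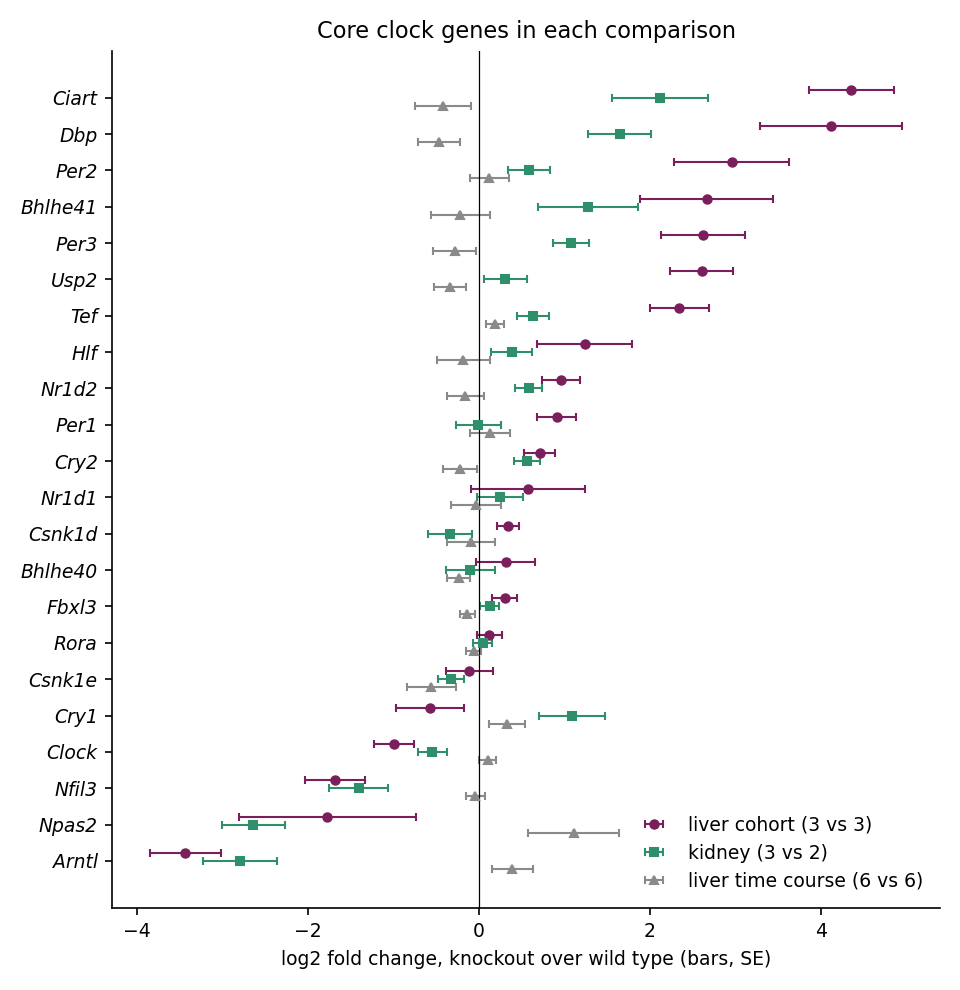
Log2 fold changes of knockout over wild type (horizontal axis, bars show SE) of core clock genes in the liver cohort (circles), kidney (squares) and liver time course (triangles). In liver they run from -3.43 for Arntl to 4.36 for Ciart, and in the time course Arntl is at 0.39.

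Acute-phase genes, which hepatocytes induce in inflammation, were lower in the knockout livers. Of 27 members, 26 were lower, with a median log2 fold change of -1.14, and 14 fell adjusted over the list alone, against 0 over all genes (Saa1 passed with both tissues in 1 fit, adjusted p = 0.0359, and without wild type 2, and Saa2 passed without wild type 1 or 2 and with no filter on low values). Saa1 was 25760 ± 27300 in the wild type and 943 ± 312 in the knockout (-4.31, SE 0.64), Saa2 21940 ± 26600 and 216 ± 62.0 (-5.93, SE 0.76), Orm2 3840 ± 3630 and 353 ± 156 (-3.02, SE 0.69) and Lrg1 2840 ± 951 and 1226 ± 230 (-1.17, SE 0.26). Wild-type liver 2 stood highest for Saa1 at 57290, against 10340 and 9662 in the other wild types and 584 to 1150 in the knockouts. Camera called the list (adjusted p = 1.05e-16; adjusted p = 0.409 with an estimated correlation), and still did so with each library left out. The 14 members past the threshold became 22 without wild type 1, 6 without wild type 2, 2 without wild type 3, 3 without knockout 1, 2 without knockout 2 and 4 without knockout 3.

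**Figure D3:**
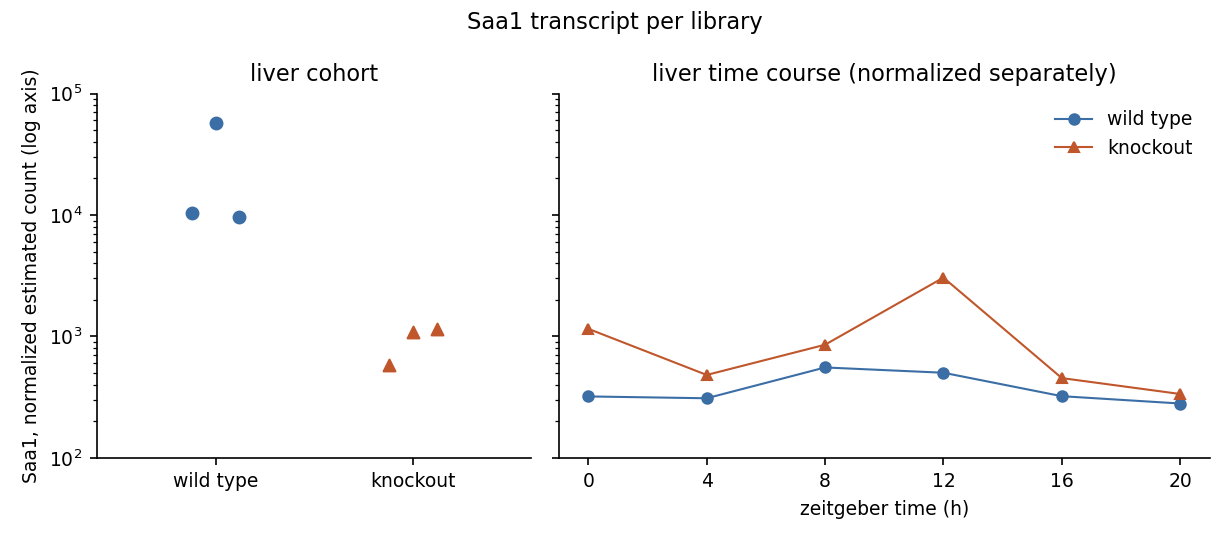
Saa1 in each library (points, normalized estimated count on a log axis) of the liver cohort and the liver time course, which were normalized separately, for wild type and knockout. Wild-type livers of the cohort lie from 9662 to 57290 and knockouts from 584 to 1150, while the highest time course library is the knockout of ZT12 at 3050.

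Camera with its preset correlation also called several metabolic and stress lists in liver. Every other split of these livers into 3 and 3 called 8 to 17 of the 44 lists as well. Lipogenic genes were higher in the knockout (17 of 21, median 0.36, adjusted p = 7.07e-05; adjusted p = 0.437 with an estimated correlation). Their regulator Srebf1 stood at 1622 ± 484 and 3533 ± 903 (1.14, SE 0.27) and Thrsp at 1.47, although 0 members passed adjusted over the list alone. Of the 76 genes for nuclear-encoded subunits of the respiratory chain, 73 were higher, by a small median of 0.17 (adjusted p = 1.03e-07; 0.641 with an estimated correlation), with Atp5j at 0.65. Small nucleolar and Cajal body RNAs, which guide modification of other RNAs, were higher (50 of 64, median 0.45, adjusted p = 3.43e-05; 0.409 with an estimated correlation). Immediate early genes were lower (14 of 17, median -0.59, adjusted p = 0.000267; 0.302 with an estimated correlation). Fos alone passed adjusted over the list alone (111 ± 77.6 and 21.17 ± 7.6, -2.18), and it did not without wild type 3, knockout 1 or knockout 3 (0 members each), while 2 members passed without wild type 1 and 3 without knockout 2. Heat shock genes were lower (16 of 22, median -0.27, adjusted p = 0.00184; 0.409 with an estimated correlation), with Hsph1 at -0.90. In all, camera called 19 of 44 lists in liver, 10 higher and 9 lower, and 0 with an estimated correlation. The calls of 9 lists, those described so far, held with each library left out. The other 10 lost theirs without at least 1 library. They were the targets of PPARalpha (33 of 39 higher, median 0.31, adjusted p = 0.00105; 0.306 without wild type 2), peroxisome biogenesis (median 0.22; 0.0557 without wild type 2), glucocorticoid response (median -0.63; 0.0829 without knockout 2), Kupffer cell and macrophage markers (median -0.24; 0.0925 without wild type 2 and 0.0548 without knockout 3), and mitochondrially encoded mRNAs (median -0.41; 0.415 without wild type 1, the library with the mitochondrial share of 7.39%, and 0.147 without knockout 1). The remaining 5 were interferon response (median -0.13; 0.354 and 0.683 without wild type 2 or 3, 0.126 without knockout 1), xenobiotic response (median 0.22; 0.848 without wild type 2 and 0.243 without knockout 1), adipocyte markers (median 0.74; 0.0825 without wild type 2), major urinary proteins (median -0.60; 0.152 without wild type 3 and 0.443 without knockout 1) and female-biased genes (median 0.44; 0.246 without wild type 2, 0.126 without knockout 1 and 0.0549 without knockout 3). With an estimated correlation the adjusted p of these 10 lists lay between 0.302 for glucocorticoid response and 0.745 for interferon response.

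G6pc, for the last enzyme of glucose release, fell in the knockout livers from 14350 ± 5480 to 4910 ± 1070 (-1.51, SE 0.28), and Gpt2, an alanine aminotransferase, rose from 6852 ± 393 to 10270 ± 1200 (0.58, SE 0.15), each adjusted over its list alone. That list, gluconeogenesis and amino acid catabolism, had 2 such members, and 1 without wild type 2 or knockout 1, 4 without wild type 3 and 0 without knockout 2 or 3. In the cell cycle list Ccnd1 (cyclin D1) rose from 262 ± 62.7 to 578 ± 28.3 (1.17, SE 0.20), a call lost without wild type 2 or any 1 knockout (0 members each), with 2 members called without wild type 3. Neither list was called by camera. The list of NAD synthesis and consumption and that of nudix hydrolases, decapping and decay had 0 members past the threshold adjusted over the list alone in liver (limma; camera adjusted p = 0.483 and 0.117), and Nudt12 stood outside both.

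In kidney, with 2 wild-type libraries against 3 knockouts, Nudt12 was the only gene of 22224 to pass the threshold. At an unadjusted p under 0.05 there were 1199 genes, where 1111 would be expected by chance, and 4564 genes did not overlap between the groups (20.5%, where chance gives 20%). The next genes by p did not pass. Gm2274 and Gm6768 were listed at 0 in both wild types; the 3 knockouts stood at 87.3, 60.4 and 168 for Gm2274 and at 58.3, 50.8 and 23.4 for Gm6768. Ugt1a10, a glucuronosyltransferase gene, was at 382 ± 101 and 1484 ± 215 (1.97, adjusted p = 0.151), Gm30948 at 9.59 ± 5.86 and 224 ± 96.7 (4.45, adjusted p = 0.151) and Mcm2, part of the replicative helicase, at 140 ± 7.43 and 576 ± 144 (2.00, adjusted p = 0.231). The authors' deposited table lists 88 genes for kidney (43 higher, 45 lower), all with the same sign here. The count of 1 became 2 without wild type 2 or knockout 1 and 0 without knockout 2 or 3.

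Clock genes again held the most members that moved in kidney. Adjusted over the list alone 10 of 23 passed (6 higher, 4 lower), and 0 over all genes tested with limma. The authors' deposited table lists 4 clock genes below an adjusted p of 0.05 in kidney (2 higher, 2 lower). Npas2 fell from 61.3 ± 1.46 to 9.14 ± 1.82 (-2.63, SE 0.36, n = 2 and 3) and Arntl from 293 ± 111 to 43.1 ± 20.9 (-2.79, SE 0.44), with Nfil3 (-1.40) and Clock (-0.54). Dbp rose from 719 ± 460 to 2017 ± 234 (1.65, SE 0.37), Ciart from 80.0 ± 64.2 to 306 ± 110 (2.12) and Per3 from 529 ± 177 to 1086 ± 50.7 (1.08, SE 0.21), with Tef (0.64), Nr1d2 (0.58) and Cry2 (0.56). The count became 2 without knockout 1 or without knockout 3, and 4 with both tissues in 1 fit. Camera called the list of E-box driven repressors and PAR-bZIP factors (11 of 12 higher, median 0.58, adjusted p = 8.3e-09), the Bmal1 arm (median -0.97, adjusted p = 0.0035; 0.123 without wild type 2) and the core clock list (median 0.31, adjusted p = 0.0483; 0.819 without wild type 2, 0.222 without knockout 1 and 0.123 without knockout 3). These 3 lists and all others called in kidney had an adjusted p = 0.579 with an estimated correlation.

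Stress and immediate early genes were lower in the knockout kidneys. Of 22 heat shock and chaperone genes 21 were lower (median -0.30, adjusted p = 2.78e-07). Hsph1, for a large cytosolic chaperone, fell from 3023 ± 296 to 1883 ± 232 (-0.69) as the one member past the threshold adjusted over the list alone, a count that was 7 without wild type 1 and 0 without any 1 of the other 4 libraries. Of 18 immediate early genes 15 were lower (median -0.57, adjusted p = 7.88e-07). Jun fell from 569 ± 61.0 to 304 ± 38.0 (-0.91), Btg2 from 597 ± 28 to 387 ± 36.0 (-0.63) and Egr1 from 186 ± 63.7 to 81.5 ± 18.9 (-1.16), among 6 members adjusted over the list alone (0 without wild type 1 or knockout 3, 1 without wild type 2 and 2 without knockout 1). The 12 markers of the distal convoluted and connecting tubule were all higher (median 0.13, adjusted p = 0.00051), with Pvalb at 249 ± 23.4 and 406 ± 37.7 (0.70) past the threshold adjusted over the list alone, a call that no fit with 1 library left out gave (0 members each). Camera called 14 of 45 lists in kidney, 7 higher and 7 lower, and 0 with an estimated correlation. The calls of 4 held with each library left out, namely E-box driven repressors, heat shock, immediate early and distal tubule.

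The other lists called in kidney lost their calls without some libraries. Mitochondrially encoded mRNAs (12 of 13 lower, median -0.38, adjusted p = 6.01e-06) stood highest in wild-type kidney 1, whose mitochondrial share was 16.06%, and the adjusted p was 0.152 without it. Plasma cell markers (12 of 14 lower, median -0.70, adjusted p = 0.000219) had an adjusted p of 0.405 without that same library, and Jchain stood at 340 ± 292 and 79.9 ± 42.0. Pancreas acinar markers (13 of 13 higher, median 2.82, adjusted p = 0.000577; 0.0591 without wild type 2) summed, without Cela1, to 6852 normalized counts in knockout kidney 3 and to at most 12.5 in the other 4 libraries, and without knockout kidney 3 the list had fewer than 3 members to test, so its call rests on that library. The list of renin, angiotensin and adrenal genes (11 of 14 higher, median 1.87, adjusted p = 0.0367; 0.152 and 0.273 without wild type 1 or 2, and 0.911 without knockout 1) was called as well, and in knockout kidney 1 the adrenal steroid hydroxylases Cyp11b1 and Cyp21a1 were at 778 and 717, against at most 1.6 in the other 4 libraries. Small nucleolar and Cajal body RNAs were higher (50 of 70, median 0.25, adjusted p = 0.00117; 0.183 without knockout 1). Glucocorticoid-responsive genes (median -0.22, adjusted p = 0.0221; 0.159 and 0.0585 without wild type 1 or 2, 0.0748 without knockout 3), cell cycle genes (median 0.17, adjusted p = 0.0439; 0.19, 0.156, 0.416 and 0.114 without wild type 1 or 2 or knockout 2 or 3) and p53 targets (median -0.18, adjusted p = 0.0439; 0.394 without wild type 1 and 0.183 without knockout 1) were called as well. Among androgen-responsive genes, a list camera did not call, Prlr (prolactin receptor) rose from 361 ± 40.6 to 1192 ± 312 (1.69) and Cyp2d9 fell from 4666 ± 542 to 3017 ± 185 (-0.63), adjusted over the list alone. These 2 calls were lost without wild type 2 (0 members), and 4 members passed without knockout 3.

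The time course asked how expression of the 2 genotypes relates to the light and dark cycle. With time as a factor, Nudt12 was the only 1 of 18702 genes to differ between 6 wild-type and 6 knockout livers, and 1120 genes had an unadjusted p under 0.05, where 935 would be expected by chance. The next genes by p, each with an adjusted p of 0.738 and the same sign at 6 of 6 times, included Rac2, a small GTPase of blood cells (95.9 ± 23.8 and 22.96 ± 17.8, log2 fold change -2.33), Cd200, an inhibitory membrane glycoprotein (5.69 ± 2.81 and 34.2 ± 13.5, 2.37), Ank3 (-0.69), Abcf1 (-0.46) and Pkig (0.80). The authors' deposited table lists 6 genes for this contrast: Nudt12, Rac2, Cd200, Pkig, Fabp2 and Cyp2c39. No core clock gene differed: 0 of 23 passed adjusted over the list alone or over all genes, and none had an unadjusted limma p under 0.05. The count of 1 gene became 0 without ZT0, ZT4, ZT12 or ZT16.

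Lipid synthesis genes stood lower in the knockouts of the time course. Of 21 lipogenic genes 15 were lower (median -0.18, adjusted p = 0.000357; adjusted p = 0.492 with an estimated correlation). Srebf1 fell from 1661 ± 462 to 1131 ± 243 (-0.53, SE 0.10), Fasn from 6682 ± 1820 to 5173 ± 1950 (-0.42, SE 0.11) and Gpam from 3594 ± 508 to 2822 ± 225 (-0.34, SE 0.09), each adjusted over the list alone and none over all genes. These 3 members became 1 without ZT0 or ZT20, and 2 without ZT8 or ZT12. Genes of the xenobiotic response were lower as well (27 of 36, median -0.17, adjusted p = 1.66e-05; 0.492 with an estimated correlation). Gsta1, a glutathione transferase, fell from 152 ± 87.8 to 64.1 ± 42.6 (-1.38) adjusted over the list alone, where the number of members past the threshold was 0 without ZT0, ZT8 or ZT12, 6 without ZT4 and 3 without ZT16. Periportal hepatocyte genes were slightly lower (13 of 15, median -0.12, adjusted p = 0.00204; 0.492 with an estimated correlation). Acute-phase genes were higher in these knockouts (24 of 27, median 0.24, adjusted p = 7.36e-08; 0.501 with an estimated correlation), with Saa1 at 381 ± 116 and 1054 ± 1020 (1.08), Fgl1 at 1466 ± 372 and 3393 ± 2000 (1.03) and C3 at 0.26, and 0 of them passed adjusted over the list alone. Pancreas acinar markers (13 of 13 higher, median 3.09, adjusted p = 1.66e-05; 0.603 with an estimated correlation) summed to 74000 normalized counts in the knockout library of ZT20, 15790 in that of ZT16, 9324 in the wild type of ZT0 and at most 842 in the other 9 libraries. Without these 3 times, which leaves 3 times with 1 library per genotype each, the adjusted p of that list was 0.836. Nudt12 then did not pass (adjusted p = 0.479) at a log2 fold change of -2.24, and over its 15 alternatives the fold change stayed between -2.36 and -2.06. Camera called 16 of 44 lists in the time course, 8 in each direction, and 0 with an estimated correlation. Other swaps of the genotypes within time points called 1 to 15 lists. The calls of the 5 lists above held with each time point left out.

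The other 11 lists did not hold in that way. Cholesterol synthesis (21 of 25 lower, median -0.13, adjusted p = 0.000641; 0.384 without ZT20), bile acid synthesis and transport (median -0.10, adjusted p = 0.00475; 0.0674 without ZT0), gluconeogenesis and amino acid catabolism (median -0.09, adjusted p = 0.00567; 0.0897, 0.0624 and 0.0551 without ZT0, ZT8 or ZT12), hepatocyte markers (median -0.10; 0.0704 and 0.0868 without ZT4 or ZT20) and erythroid markers (median -0.28; 0.0561, 0.0962 and 0.153 without ZT8, ZT12 or ZT20) were lower. Interferon response genes (28 of 35, median 0.19, adjusted p = 0.00142; 0.0885 and 0.104 without ZT0 or ZT4), antigen presentation (18 of 20, median 0.11; 0.381, 0.308 and 0.0701 without ZT0, ZT4 or ZT12), stellate cell markers (median 0.14; 0.113 and 0.0553 without ZT0 or ZT4), heat shock genes (median 0.10; 0.0685, 0.175 and 0.207 without ZT0, ZT12 or ZT16), the Bmal1 arm (median 0.24; 0.0599 and 0.111 without ZT4 or ZT12) and adipocyte markers (median 0.76; 0.384, 0.0552, 0.0935, 0.0671 and 0.0702 without ZT0, ZT4, ZT12, ZT16 or ZT20) were higher. With an estimated correlation each of these 11 had an adjusted p of 0.492 or more.

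Daily rhythms were strong in the livers of the time course, with both genotypes fitted by 1 curve. Rhythmic genes numbered 1085 of 18702, of which 16 were core clock genes. Arntl had a log2 amplitude of 2.44 with its peak at 22.3 h after lights on (adjusted p = 0.000569), Npas2 2.75 at 0.1 h, Nr1d1 (REV-ERBalpha) 3.36 at 7.6 h, Dbp 3.08 at 9.8 h, Ciart 3.24 at 11.7 h, Per1 2.66 at 13.0 h, Per2 1.86 at 15.7 h and Cry1 1.58 at 19.2 h. Among the genes with the smallest p were Clpx (amplitude 1.39, peak 23.3 h, adjusted p = 4.45e-07), Gpcpd1, Eif4ebp3, Fkbp4, Dbp, Hspa8, Por, Insig2 and Ciart. Peaks of rhythmic genes were spread over the day, with 165, 294, 268 and 358 genes in the successive 6 h from ZT0 on. The number of rhythmic genes was 608, 674, 513, 475, 613 or 565 without ZT0, ZT4, ZT8, ZT12, ZT16 or ZT20.

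No gene passed the test of a different rhythm between the genotypes. With limma 0 of 18702 genes passed the interaction test, and 894 had an unadjusted p under 0.05, where 935 would be expected by chance. Among the 1085 rhythmic genes, peaks in the knockout differed from those in the wild type by a median of -0.08 h, with a median absolute difference of 0.85 h, and for the 16 rhythmic clock genes from -1.5 to 1.76 h with a median of 0.39 h. These genes were chosen by 1 curve for both genotypes, which favours genes of similar rhythm, so small differences among them do not show that rhythms were alike. Of all 23 clock genes the smallest unadjusted limma p was 0.0491, for Cry1 (0.725 adjusted over the list alone). In simulated data with 200 such genes, the same test found 88% of genes whose rhythm of log2 amplitude 2 was opposite in the genotypes. At amplitude 1 it found 52.5%. With fewer such genes the adjustment is stricter, and the shares could be lower. Shifts of a few hours were not simulated, so these shares do not apply to them.

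**Figure D4:**
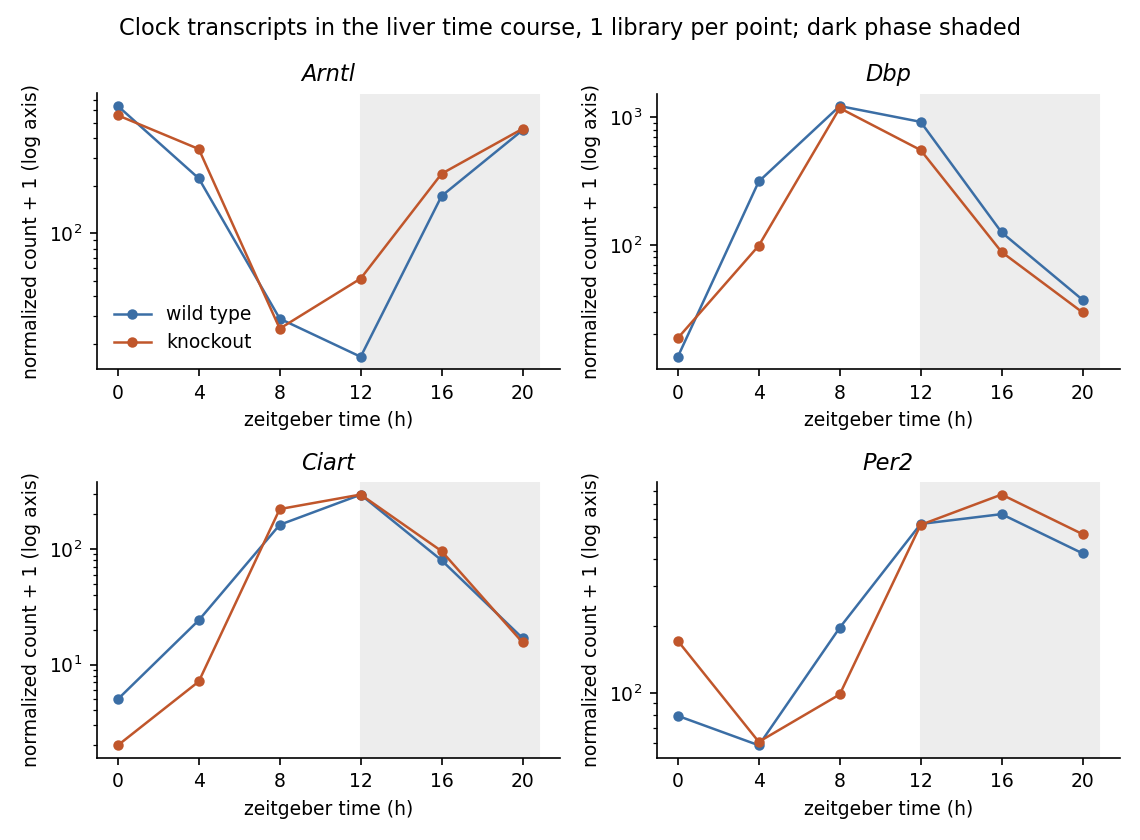
Arntl, Dbp, Ciart and Per2 in the liver time course (normalized count + 1 on a log axis against zeitgeber time in hours), with 1 library per point, wild type in blue and knockout in orange, and the dark phase shaded. Peaks fitted to both genotypes lie at 22.3 h for Arntl, 9.8 h for Dbp, 11.7 h for Ciart and 15.7 h for Per2.

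The knockout effect in the liver cohort differed from that in the time course for 7 of 18029 genes (the log2 fold change was more positive in the liver cohort for 3 and more negative for 4). These were the clock genes Arntl (difference of log2 fold changes -3.82, SE 0.50), Ciart (4.77, SE 0.63) and Usp2 (2.94, SE 0.41), the acute-phase genes Saa2 (-7.36, SE 1.0) and Saa1 (-5.38, SE 0.74), and Upp2 (2.44, SE 0.34), each with an adjusted p of 0.0196, and AI506816 (-3.70, SE 0.52, adjusted p = 0.0222). At an unadjusted p under 0.05 there were 1879 genes, where 901 would be expected by chance. Adjusted over the list alone, 13 of 23 clock genes differed. By camera 20 of 44 lists differed and 0 with an estimated correlation. E-box driven repressors had a median difference of 2.49 (adjusted p = 2.56e-15; 0.0848 with an estimated correlation) and acute-phase genes one of -1.25 (adjusted p = 1.21e-19; 0.181 with an estimated correlation). Lipogenesis had 0.46 (adjusted p = 3.96e-07). The count of 7 was 130 without wild-type liver 1, 12 without wild-type liver 3, 2, 4 and 0 without knockout liver 1, 2 or 3, 13 without ZT0, 0 without ZT4 and 2 without ZT12. Without knockout liver 1, knockout liver 3 or ZT4, none of these 7 genes kept its call. Calls were also lost without knockout liver 2 (Saa1, Saa2, Upp2, AI506816), wild-type liver 2 (Arntl, Usp2, Upp2, AI506816), wild-type liver 3 (Usp2), ZT12 (Ciart, Saa1, Usp2, Upp2, AI506816), ZT16 (AI506816) and ZT20 (Usp2, AI506816), and all these lost calls had an adjusted p between 0.0502 and 0.0725. Across 18028 genes, which are not independent replicates, the log2 fold changes of both liver sets correlated at r = -0.078 (Spearman's rank correlation -0.097), with 45.7% of genes of the same sign. Of 138 genes with an unadjusted p under 0.05 in both sets, where 89.7 would be expected, 33 had the same sign.

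Liver and kidney shared more. Across 18353 genes, again not independent replicates, r was 0.198 (rank correlation 0.161), and 56.4% had the same sign. Among 190 genes with an unadjusted p under 0.05 in both tissues, where 79.8 would be expected, 160 had the same sign (79 higher, where 19 would be expected, and 81 lower, where 21 would be expected). For the 23 clock genes r was 0.867 (rank correlation 0.819). For 1051 genes called rhythmic in the time course r was 0.504, against 0.178 for 17302 genes not called rhythmic. Labels give no hour of collection for these samples and do not say whether both tissues came from the same mice. Shared mice or hours could thus also give this overlap, which was not tested. Named by the larger of both p, the shared genes included Gm30948, Gm38246, Hist1h4a (3.03 in liver and 3.83 in kidney), AI506816 (-2.71 and -3.01), Arntl, Slc25a25 (-1.47 and -0.70), Ttc28 (-1.92 and -1.05) and Tmem246 (3.64 and 1.18). The knockout effects of the 2 tissues differed for 1 of 18354 genes, Eci3 (difference 6.25, SE 0.65, adjusted p = 0.0245), which stood at 5379 ± 1220 in wild-type kidney and 4320 ± 291 in knockout kidney. At an unadjusted p under 0.05 there were 810 genes, where 918 would be expected by chance. The difference was 7.74 with a pseudocount of 0.1 (adjusted p = 0.451) and 4.68 with 5, and the adjusted p ran from 0.00285 to 0.451 over its 16 alternatives. This call was also lost without wild-type liver 3 (adjusted p = 0.13), knockout liver 2 (0.0997), wild-type kidney 1 (0.0622) or 2 (0.0723), or knockout kidney 1 (0.117), 2 (0.135) or 3 (0.134). The number of genes was then 2 without wild-type liver 1, knockout liver 1, knockout liver 3 or wild-type kidney 1, and 0 without wild-type liver 3, knockout liver 2 or any 1 knockout kidney. Of the clock genes, Usp2 differed between the tissues (2.30, 0.0177 adjusted over the list alone). Camera called 6 of 35 lists for this difference, and 0 with an estimated correlation (adjusted p = 0.812).

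Labels give no hour of collection and no light schedule for the liver cohort. The internal time of each liver was therefore read from 16 rhythmic clock genes of the time course. On the zeitgeber scale of the time course, the wild-type livers were placed at 4.8, 2.7 and 2.5 h (mean 3.3, SD 1.27, n = 3). The knockout livers were placed at 10.5, 9.1 and 7.7 h (mean 9.1, SD 1.40, n = 3). The difference of 5.8 h had an exact two-sided permutation p of 0.10, the smallest that 3 against 3 can give. For time course libraries with their own time left out, the median absolute error was 0.65 h and the largest 2.4 h. This error does not cover the step to the liver cohort, which was younger and normalized separately. The best correlations in that cohort were 0.86, 0.721 and 0.707 in the wild types and 0.93, 0.93 and 0.861 in the knockouts. In the time course itself the knockout library was placed later than the wild type of the same time by -0.2, -1.2, 0.1, 1.1, 0.2 and 0.5 h (mean 0.08, SD 0.77, n = 6, exact sign-flip permutation p = 0.8125).

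**Figure D5:**
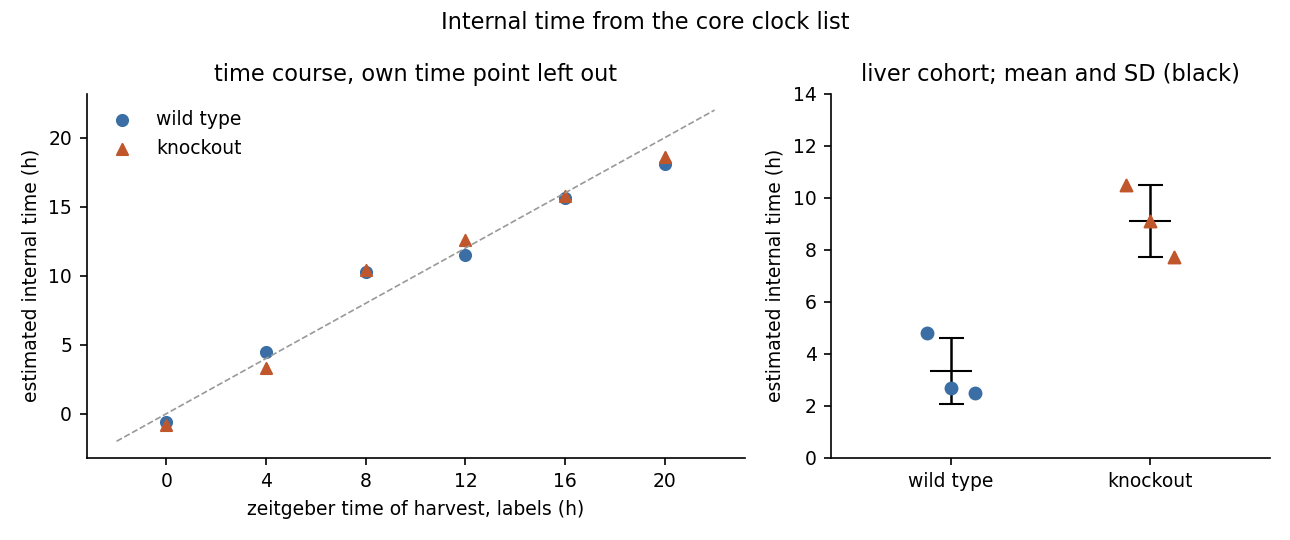
Left, internal time estimated from clock genes (hours) against the labelled zeitgeber time of the 12 time course libraries, each with its own time point left out of the reference, and a dashed line where both are equal. Right, estimates for the 6 livers without a time label, with mean and SD in black; wild types lie at 2.5 to 4.8 h and knockouts at 7.7 to 10.5 h.

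The founders were B6D2F1/J hybrids crossed with C57BL/6J, and genes near the edited locus were therefore compared with all others. Within 20 Mb of Nudt12 on chromosome 17, 0 genes other than Nudt12 passed the threshold in liver, kidney or the time course (limma; Fisher's exact p = 1 in each). In liver 2 of 276 genes in that window had an unadjusted p under 0.01, against 388 of 18728 elsewhere (odds ratio 0.345, 95% interval 0.0414 to 1.27, Fisher's exact p = 0.135).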

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

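The tests of a clock shifted by the knockout, of a single wild-type library, of an effect of the knockout at any age and hour, of pancreatic tissue, of the fitted curves for Upp2, AI506816 and Eci3 and of the 16 clock genes with times from 90 other genes, and the fits with 1 library or time point left out for the difference between the liver cohorts, were chosen after the result was seen.

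The effect of the knockout on clock genes differed between the liver cohort and the time course, by -3.82 for Arntl, 4.77 for Ciart and 2.94 for Usp2 (log2), and for 13 clock genes over the list alone. A clock shifted by the knockout itself is argued against by the time course, where knockout and wild type of the same hour were placed at most 1.2 h apart, against 5.8 h in the liver cohort. A candidate explanation is that the wild-type and knockout livers of the cohort were collected at different hours: across 16 rhythmic clock genes, which are not independent replicates, the log2 fold changes correlated at r = 0.88 with those that the fitted curves give between the mean internal times, although these times came from the same genes (r = 0.864 with times from 90 other genes). With times from the clock genes, 15 of these 16 genes had the same sign. Sizes differed, with a median of 1.49 from the curves where 0.74 was observed. The curves gave 3.56 for Per1 where 0.91 was observed, and 1.57 for Per2 where 2.95 was observed. For 1065 rhythmic genes outside the clock list r was 0.347 (rank correlation 0.504, 71.7% of the same sign), which leaves open how far an hour of harvest would account for them. Age differed between the cohorts, and labels give a light schedule for the time course only. Neither age nor light schedule was tested, and both remain open.

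Acute-phase genes also differed between the cohorts, by -7.36 for Saa2 and -5.38 for Saa1. A single wild-type library is argued against as the whole cause, since 24 of 27 members were lower without wild-type liver 2. For different hours of harvest the curves give a median log2 fold change of 0.207 where -1.14 was observed. Saa1 and Saa2 did not pass the rhythm test, however (adjusted p = 0.349 and 0.677). Curves of such genes are uncertain, so these values cannot decide on the hour of harvest. For a loss of Nudt12 that acts in liver at any age and hour, the time course gave the other sign, with a median of 0.237. That list had a camera adjusted p of 0.501 with an estimated correlation. Saa1 was at most 555 in the wild types there, well below those of the cohort (normalized separately). A lower induction could not have shown at such levels, so the time course cannot decide. An effect of the knockout at the younger age, and the inflammatory state of single mice or of a cage, may each remain as explanations and were not tested.

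Transcripts of pancreatic enzymes stood out in single libraries: Ctrb1 was at 485 in the wild type of ZT0 and 5530 in the knockout of ZT20, and Prss2 at 314 and 3330 in the same libraries, each far from the rest of its group. Pancreatic tissue in these samples is a candidate source. All 12 measured members of the list other than Cela1 were highest in the knockout of ZT20, and likewise 12 of 12 in knockout kidney 3 within its table. No biological explanation was tested.

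Single libraries far from the others of their group were found in 12 of 48 checks of the time course, where chance marks about 1 in 20 groups of replicates, and several of the 12 share a library or a gene group. The 6 libraries of a group are 6 different times, however, so the checks do not tell a stray library from a change over the day. Besides the pancreatic genes these were Saa1 at 3050 and Saa2 at 1370 in the knockout of ZT12 (next 1150 and 368), C3 at 119000 in the wild type of ZT12 (next 94200; also highest at ZT12 in the knockout, at 160000), and Ank3 at 1080 in the wild type of ZT8 (next 522; also highest at ZT8 in the knockout). Gm30948 was at 439 in the wild type of ZT8 and 324 in the knockout of ZT0. The knockout library of ZT0 had about 22.3 M estimated reads (next 17.8), and the wild type of ZT8 had the fewest genes above 0, at 18300 (next 19400).

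Between the liver cohort and the time course the knockout effect also differed by 2.44 for Upp2 and -3.70 for AI506816, and for 20 gene lists (0 with an estimated correlation). Between the mean internal times of the liver cohort the fitted curves give 1.99 for Upp2, where 2.10 was observed in that cohort, and 1.23 for AI506816, where -2.71 was observed. Between liver and kidney it differed by 6.25 for Eci3, for 1 clock gene over the list alone and for 6 gene lists (0 with an estimated correlation). For Eci3 in liver the curves give 3.02, where 5.95 was observed, although Eci3 did not pass the rhythm test (adjusted p = 0.162).

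Other splits of the same samples were counted for the comparisons named here, and none were run for kidney, with 2 wild-type libraries, or for liver minus kidney. For the 7 genes that differed between the liver cohorts, 2 of 100 splits gave as many, the real one included, a share under 0.05 that makes chance less likely. The other split gave more than the real one (highest other 8), though, and the real count was 0 without knockout liver 3 or ZT4, 2 without knockout liver 1 or ZT12, 4 without knockout liver 2, 12 without wild-type liver 3, 13 without ZT0 and 130 without wild-type liver 1. For the 16 lists of the time course 1 of 32 splits gave as many, the real one alone, a share under 0.05 and the smallest that 32 splits can give. The margin was 1 list (highest other 15), though, and without ZT0, ZT4 or ZT12 the count was 9, 10 and 10, which several other splits of all 12 libraries reach, and with an estimated correlation it was 0. For the number of genes called in the time course 3 of 32 splits gave as many as the real 1 (highest other 1), so chance cannot be excluded for the number. This says nothing against the gene itself, Nudt12, which was lower in the knockout at 6 of 6 times (log2 fold change -2.17, SE 0.19). For differential rhythm the real count was 0, which all 32 splits reach whatever they give (highest other 0), so that count tests nothing. The 10 splits of the 6 livers are too few for a share under 0.05. Among them 3 gave as many genes as the real 3 (highest other 6). As many lists as the real 19 came from 1 (the others 8 to 17), and as many clock genes over the list alone as the real 14 from 1 (highest other 1).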

How the results depend on the processing

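The filter at a mean of 10, robust variance priors and the fits without the 3 times with pancreatic transcripts were chosen after seeing the data, as was the extension of further settings to some results. Of 225 alternatives for the main counts and values, 149 stayed within 1.5 times the count or within the spread and 76 moved. Of 3999 for single genes and lists, 3721 stayed on their side of the threshold. Another 255 were no longer past it, 19 came past it and 4 were reversed. A change of sign counted as reversed only where the main fit or the alternative called the result. Genes called in neither could thus change sign unseen, as Usp2 did in kidney (log2 fold change from -0.144 to 0.759). Differential rhythm gave 0 genes in each alternative run, and internal time a difference of 5.8 h, or 5.2 h with 100 rhythmic genes as reference. The low depth of the time course (from about 12.5 M estimated reads) limits genes of few counts. Unless stated, the cause of a change was not tested.

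With no filter on low values, more genes are tested and liver had 8 genes and kidney 0. With a mean of at least 10 liver had 1, kidney 0 and the difference between the liver cohorts 21, with fewer genes tested. A pseudocount of 0.1 gave 1 in liver, 2 in kidney and 0 for liver minus kidney, and robust priors gave 2 in kidney. Both tissues in 1 fit, which shares the spread, gave 55 in liver, 2 in kidney and 4 kidney clock genes. Gene lists fell to 0 in liver, kidney and the time course alike with an estimated correlation and with fry for 1 direction. The mixed form of fry, which lets members move either way, called 5 lists in liver, 8 in kidney and 2 in the time course. Among them was the core clock list in liver (mixed fry, adjusted p = 0.019) and in kidney (0.0219), but not in the time course. Without the 3 times with pancreatic transcripts, which leaves fewer samples, the time course had 0 genes. Rhythmic genes numbered 6 in the wild type only and 17 in the knockout only, from 6 libraries each. Among genes with an unadjusted p under 0.05 in either set, r was -0.106 for the liver cohorts and 0.293 for liver and kidney.

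With 1 library or time point left out, the counts ran from 0 to 2 in kidney (clock genes 2 to 14, lists 10 to 14), 0 to 38 in liver (clock genes 12 to 16, lists 14 to 25), 0 to 1 in the time course (lists 9 to 18), 0 to 2 for liver minus kidney, 0 to 130 between the liver cohorts and 475 to 674 for rhythmic genes; r ran from -0.108 to -0.045 between the liver cohorts and from 0.141 to 0.204 between liver and kidney. Where wild-type kidney was left with 1 library, that library was assumed to vary like the knockouts. Reversed were the list of renin, angiotensin and adrenal genes in kidney without knockout 1 (adjusted p = 0.911; others from 0.00182), the xenobiotic list in liver without wild type 2 (0.848; others from 0.000196), and the adipocyte and pancreas lists of the time course without the 3 times with pancreatic transcripts (0.836 each).

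Time as a block was part of the main design, since the time course numbers mark shared hours. With no block for time, 1 gene, 0 clock genes and 13 lists were called, against 1, 0 and 16. Numbers of the liver and kidney libraries pair nothing. Not run, as they need counts, were edgeR, DESeq2, limma-voom and other size factors. A single fit of knockout effects in both liver cohorts together was foreseen for counts only and was not run either. The joint limma fit of both cohorts served the difference of their effects. The wild-type libraries alone gave too few clock genes past the threshold for a reference for internal time, and so no value. In the rhythm test of the wild type only, 2 clock genes passed.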

Other observations

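The test of genes with an unadjusted p under 0.01 near Nudt12 was chosen after the result was seen, and the genes of the next paragraph that fall outside the naming rule were chosen after their values were seen.

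Some histone genes of the replication-dependent clusters were higher in the knockouts of both tissues. In liver Hist1h2bl rose from 3.48 ± 1.85 to 41.4 ± 8.07, Hist1h2bq from 28.6 ± 14.2 to 200.1 ± 77.0 and Hist1h4a from 7.28 ± 2.40 to 70.4 ± 33.0 (n = 3 and 3; 3 genes adjusted over the list alone, 0 over all genes with limma, and these 3 over all genes with both tissues in 1 fit, with adjusted p of 0.0131 for Hist1h2bl and 0.0339 for the others). In kidney Hist1h4a rose from 9.17 ± 3.58 to 152 ± 73.1, Hist1h2bq from 92.1 ± 37.9 to 362 ± 136 and Hist1h2bl from 12.9 ± 5.88 to 54.0 ± 11.6, while Hist1h2bc fell from 2401 ± 41.8 to 1665 ± 148 (n = 2 and 3; 5 genes adjusted over the list alone). The liver count was 5 without wild type 1, and the kidney count was 0 without wild type 1, wild type 2 or knockout 3, and 1 without knockout 1 and 3 without knockout 2. The list as a whole was not called by camera (adjusted p = 0.111 in liver, 0.329 in kidney and 0.109 in the time course). These genes lie in families of near-identical copies, so estimated counts can be split among them in ways that differ between libraries.

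Adrenal transcripts were highest among the livers in the knockout of ZT0, with Cyp11b1 at 185 and Cyp21a1 at 178. In the other 11 time course libraries Cyp11b1 was listed at 0 but Cyp21a1 at 3.35 to 61.2, and in the 6 livers of the cohort, normalized separately, Cyp11b1 was listed at 0 and Cyp21a1 at 10.9 to 52.6. Hc, a complement gene for which DBA/2J mice are deficient, was at 26.5 ± 3.26 in wild-type and 6.82 ± 0.235 in knockout kidney (n = 2 and 3; 1 gene adjusted over the list of genes that differ between DBA/2J and C57BL/6J alone, and 0 without any 1 of the 5 libraries). With both tissues in 1 fit, Hc was with Nudt12 one of the 2 genes called in kidney over all genes (log2 fold change -1.81, adjusted p = 0.00598), while in liver it was not called there (-0.58, adjusted p = 0.185).

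DBA/2J alleles linked to the edited locus could give called genes around Nudt12. Within 20 Mb none other than Nudt12 was called in liver, kidney or the time course, and with so few calls anywhere (Fisher's exact p = 1 in each) the test cannot tell. For liver genes with an unadjusted p under 0.01 the upper 95% limit of the odds ratio was 1.27 within 20 Mb and 0.909 within 40 Mb, but 3.6 within 10 Mb, and within 20 Mb it was 2.06 in kidney and 2.38 in the time course. No enrichment was found in these windows, but an excess of linked genes closer to Nudt12, or in the other sets, is not excluded and remains open.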
